A study of Mus musculus with 9 samples.

How the data were processed

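RNA-seq libraries of white fat, brown fat and soleus muscle were studied, 3 of each, from wild-type C57BL/6J male mice aged 3 months. Per the labels' protocols, total RNA was taken up in TRIzol and libraries were made with the Illumina TruSeq RNA kit, version 2. Per the submitters' processing notes, reads were handled with TopHat 1.4.1 and Cufflinks 2.0.1 on the mouse build mm9. The authors deposited a single matrix of FPKM values with 18401 rows, each named by RefSeq transcript accessions, and 9 columns whose names match the sample labels. FPKM divides fragments by transcript length and by the mapped total of the library, so a few very abundant transcripts lower all others. The sum of FPKM ran from 213936 in white fat replicate 2 to 352502 in soleus replicate 2. The 20 highest genes held 14.8% to 16.1% of it in white fat, 18.7% to 19.0% in brown fat and 27.8% to 29.3% in soleus.

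Accessions were matched to gene symbols, with 18305 rows named from a RefSeq gene table and 38 from a GENCODE table of RefSeq matches. The 55 rows without a symbol and 3 rows with several were left out, and they held 0.0339% to 0.360% of the FPKM of a library. The 541 symbols with more than 1 row were summed, giving 17753 genes. The gene table belongs to another build than mm9, so it was used for names alone and no coordinates are given. Genes with near-identical copies or pseudogenes, such as Gapdh, ribosomal protein genes and small subunits of the respiratory chain, are uncertain, because reads that fit several places may have been divided or dropped. Exact zeros can be failed estimates of Cufflinks, so a gene at 0 in a whole tissue is described only as listed at 0.

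Read totals were not given. Where low values are whole multiples of what 1 fragment is worth, the commonest ratio of values at or under 0.3 FPKM between 2 libraries gives their relative depth. For 34 of the 36 pairs of libraries these ratios were within 0.03 log2 units of a single chain of depths. The relative depths were 2.77, 1.59 and 1.52 in brown fat, 1.39, 1 and 3.56 in white fat and 2.35, 1.66 and 1.44 in soleus, for replicates 1, 2 and 3, with the lowest set to 1. No counts were used in a test.

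All 9 libraries were fitted together on log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, with a mean-variance trend and 6 residual degrees of freedom, on 9913 genes with at least 1 FPKM in at least 3 libraries. Fold changes are on this scale, which understates the change of genes with low values. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each of the 3 tissue comparisons. A gene was called at an adjusted p under 0.05, and was selective for a tissue if called with a log2 fold change of at least 1 against both others. Gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over 108 tests of the 36 lists that had at least 3 tested members. In all, 42 lists were fixed. Camera called 61 of the 108 tests. With a correlation estimated from the data it called 0, with 14 at an unadjusted p under 0.05 and adjusted p-values from 0.27 to 0.98, and fry called 97 for a shift in one direction. Fry asks whether a list's genes move on balance one way and does not compare them with other genes, so ranges of a list's adjusted p are over the camera tests alone, with preset or estimated correlation.

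The main tests, the lists, most alternatives and the rule for naming genes were set before the data were examined, and tests and alternatives chosen later are named as such. Named genes were Kdm6a, Ezh1, Ezh2 and Ucp1, beside the gene in the study's title, whose values are not reported here. To these were added the 5 genes per direction with the largest fold change among those with a mean of at least 10 FPKM in the higher tissue, and the 10 most selective genes per tissue by the smaller of their 2 fold changes. From each described list came the 2 called genes with the largest change per direction and the member with the highest mean, and from each tissue the 5 highest genes. Where this rule met a gene listed at 0, the next genes in line were taken, except among selective genes, where such genes were kept and marked. This choice was made after the zeros were seen, as was the naming of all genes listed at 0 and of Gapdh.

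The fit was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 log2 unit in each comparison. The changed genes were drawn only from those above a minimum mean value, with independent noise, so recovery of genes with low values was not tested. It recovered 75% and 98% of them in brown against white fat, 76% and 98% in brown fat against soleus, and 74% and 99% in white fat against soleus, with 8, 3 and 15 false calls. Alternatives covered the pseudocount, the filter, upper quartile, median of ratios, quantile and TPM scaling, the libraries in the fit, the variance model, the replicate number as a block, each library left out in turn, and the treatment of symbols with several rows. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.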

Results

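Transcript levels were measured by RNA-seq in white fat, brown fat and soleus muscle of wild-type male C57BL/6J mice aged 3 months. Brown fat burns fuel to make heat, white fat stores lipid, and the soleus is a postural muscle of the hind limb. Each tissue had 3 libraries, 9 in all, and the labels state 3 mice without saying which libraries share a mouse. The depot that the white fat came from was not given in the sources used here. Values are FPKM (sequenced fragments scaled to the length of the transcript and to the mapped total of the library), given as mean ± SD over the 3 libraries of a tissue unless stated otherwise. Read totals were not given, but the spacing of low values put the relative depth of the libraries between 1 (white fat replicate 2) and 3.56 (white fat replicate 3). Each library had between 8487 and 9305 genes at 1 FPKM or more, and 9913 genes entered the tests.

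The 9 libraries fell into their 3 tissues. Libraries of the same tissue correlated across genes with a Pearson r of 0.988 to 0.995, brown with white fat at 0.811 to 0.823, brown fat with soleus at 0.674 to 0.713, and white fat with soleus at 0.568 to 0.617. The first principal component held 69.5% of the variance and separated muscle from fat, and the second held 28.2% and separated brown from white fat. The genes with the highest listed values differed in kind between the tissues. In brown fat they were Cox8b, Car3, Atp5b, Ucp1 and Cox6a1, of which Cox8b, Atp5b and Cox6a1 encode subunits of the respiratory chain and ATP synthase, and Ucp1 encodes the uncoupling protein of heat production. In white fat they were Mir703, Adipoq, Dbi, Retn and Hp, with Adipoq and Retn encoding the fat hormones adiponectin and resistin. Mir703, a microRNA gene, stood at 3911, 3252 and 4729 FPKM in white fat replicates 1, 2 and 3. FPKM divides by transcript length, and whether a short transcript raised the Mir703 values was not tested. In soleus the highest genes were Tnnc2, Myl2, Tnni2, Mylpf and Myl3, all troponin or myosin light chain genes of the contractile apparatus. Genes whose estimates may have failed in a tissue, described below, could not rank there.

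**Figure D1:**
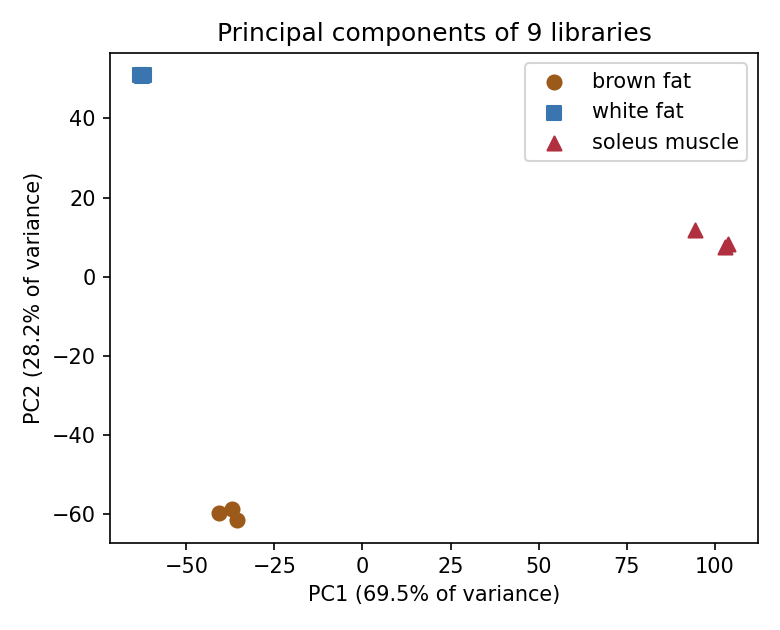
Principal component scores of the 9 libraries on log2(FPKM + 1), PC1 on the horizontal and PC2 on the vertical axis, 1 point per library. PC1 held 69.5% and PC2 28.2% of the variance, and the 3 libraries of each tissue lie together.

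Some abundant genes were listed at exactly 0 FPKM in all 3 libraries of a tissue. Fabp4 and Scd1, both genes of lipid handling, were listed at 0 in brown and white fat, and Fasn was listed at 0 in brown fat. Car3, Cfd, Lpl and Gsn were listed at 0 in white fat, and Acta1, Ckm and Tnnt3 were listed at 0 in soleus. Mb was listed at 0 in soleus too, but its mean stayed under 10 FPKM in both kinds of fat. Gapdh, a gene that every cell uses, stood at a mean of only 1.10 FPKM in brown fat, 0.359 in white fat and 1.73 in soleus. No fold change is given against a tissue listed at 0, and the counts of genes changed by at least 1 log2 unit and of called list members below say how many rest on one.

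Brown fat against white fat asked which transcripts separate the heat-producing from the storing tissue. Ucp1 stood at 3685 ± 377 FPKM in brown fat (SD, n = 3) and 15.0 ± 18.2 FPKM in white fat (SD, n = 3), where replicates 1, 2 and 3 held 7.81, 1.45 and 35.7 FPKM. Cidea, a lipid droplet protein gene, stood at 2193 ± 149 against 12.4 ± 12.3 FPKM, and the complex IV subunit gene Cox8b at 6387 ± 305 against 66.0 ± 41.5 FPKM. In the other direction, Sncg, which encodes gamma-synuclein, stood at 10.9 ± 0.919 FPKM in brown and 1192 ± 76.9 FPKM in white fat, the angiotensinogen gene Agt at 1.08 ± 0.240 against 191 ± 14.5 FPKM, and the resistin gene Retn at 108 ± 18 against 2526 ± 474 FPKM. Over all genes, 3769 were higher and 3446 lower in brown fat at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 1232 and 1387 of them by at least 1 log2 unit, numbers that were 813 and 3352 with TPM rescaling and 773 and 631 with a pseudocount of 5. Of the called genes 52.2% were higher in brown fat, but 21.3% after rescaling to a common total (TPM), with 1898 higher and 6993 lower, which moved the median log2 fold change of all genes from 0.03 to -0.52. Of those changed by at least 1 log2 unit, 10 higher and 11 lower genes rested on a tissue listed at 0.

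All 23 tested genes of the thermogenic list rose in brown fat over white fat, over all genes tested and also adjusted over the list alone, with a median log2 fold change of 4.79. Ucp1 differed by 8.63 log2 units (SE 0.77, limma adjusted p = 2.0e-06), Cidea by 7.77 (SE 0.49, adjusted p = 1.3e-07) and Cox8b by 6.76 (SE 0.35, adjusted p = 2.8e-08). Otop1, which encodes a proton channel, stood at 86.2 ± 8.85 against 0.437 ± 0.426 FPKM. The list stood out from other genes by camera with a preset correlation (adjusted p = 7.4e-11), though not with the correlation estimated from the data (adjusted p = 0.33 with an estimated correlation). Of 23 tested genes of the white fat list, 20 were lower and 1 was higher in brown fat, the same numbers adjusted over the list alone (camera adjusted p = 6.9e-07, and adjusted p = 0.33 with an estimated correlation). The higher one was Cfd, listed at 0 in white fat, and 1 of the lower ones was listed at 0 in brown fat. The leptin gene Lep stood at 9.38 ± 3.69 FPKM in brown and 219 ± 5.35 FPKM in white fat, a difference of -4.47 log2 units (SE 0.44, limma adjusted p = 4.5e-06). Nnat, which encodes neuronatin, stood at 9.55 ± 2.41 against 977 ± 273 FPKM. Among genes that both kinds of fat use, 13 of 22 tested rose in brown fat, 1 of them (Lpl) listed at 0 in white fat, and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.030, and adjusted p = 0.60 with an estimated correlation). Without white fat replicate 1 or replicate 3 this list missed the threshold (camera adjusted p = 0.058 in each case, over a range of 0.021 to 0.60 in camera tests). Agpat2, a gene of triglyceride synthesis, was 2.20 log2 units higher (SE 0.21), whereas the adiponectin gene Adipoq fell from 2876 ± 266 FPKM in white to 1008 ± 88.8 FPKM in brown fat.

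**Figure D2:**
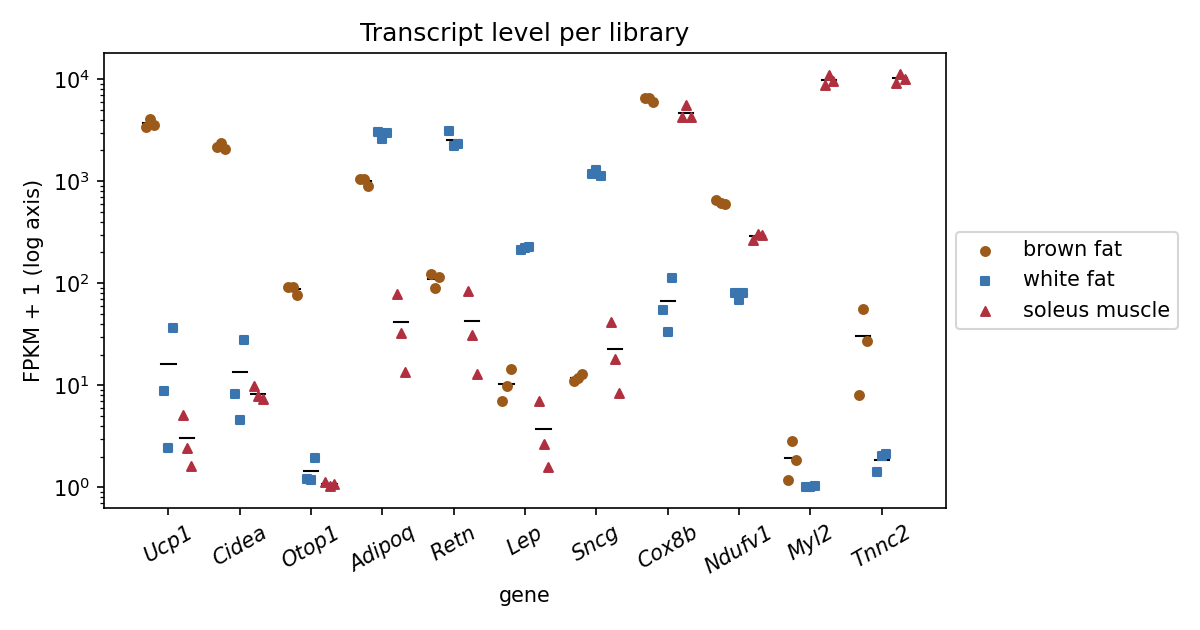
FPKM + 1 on a log axis for 11 genes in each of the 9 libraries, with markers for the tissues and a black line at the mean of 3. Ucp1 and Cidea are highest in brown fat, Lep and Sncg are highest in white fat, Cox8b and Ndufv1 are lowest in white fat, and Myl2 and Tnnc2 reach means of 9797 and 10208 FPKM in soleus.

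Genes of the mitochondrial machinery rose together in brown fat against white fat. All 35 tested genes of respiratory complex I were higher, with a median of 2.33 log2 units, as were all 14 of complexes II and III (median 2.72), all 15 of complex IV (median 2.42) and all 19 of the tricarboxylic acid cycle (median 2.85). The numbers were the same adjusted over each list alone, and camera called all 4 lists (adjusted p = 3.3e-13, 7.2e-08, 1.3e-06 and 1.7e-10). With an estimated correlation none of them passed, at an adjusted p = 0.39, 0.38, 0.38 and 0.36. The complex I gene Ndufv1 stood at 616 ± 27.7 FPKM in brown and 75.2 ± 7.01 FPKM in white fat, Uqcrc1 of complex III at 998 ± 14.5 against 109 ± 10.9, and the citrate cycle gene Sucla2 at 1049 ± 46.6 against 55.6 ± 4.05. Of 15 genes of fatty acid oxidation 14 rose, Acaa2 by 4.35 log2 units (SE 0.10) and Hadhb by 4.04 (SE 0.08), and Cpt1a, the liver form of the carnitine transferase, fell by 2.45 (SE 0.09) (camera adjusted p = 3.7e-07, and adjusted p = 0.27 with an estimated correlation). The ATP synthase list parted, with 12 of 15 genes higher and 3 lower (camera adjusted p = 0.0073, and adjusted p = 0.60 with an estimated correlation). Atp5a1, of the catalytic head, was 2.55 log2 units higher (SE 0.11), while Atp5g1, of the membrane ring, stood at 1.46 ± 0.176 against 9.13 ± 2.18 FPKM and Atpif1, which encodes an inhibitor of the enzyme, at 21.5 ± 1.20 against 65.3 ± 2.12 FPKM. Glycolysis genes were higher too, 16 of 18 against 1 lower (camera adjusted p = 8.9e-06, and adjusted p = 0.27 with an estimated correlation), with Ldhb at 390 ± 11.5 against 30.3 ± 3.97 FPKM and Pfkl at 177 ± 4.39 against 19.3 ± 2.52 FPKM.

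Markers of macrophages, of matrix and of mesothelium were lower in brown than in white fat. All 11 tested macrophage markers fell, with a median of -3.23 log2 units (camera adjusted p = 2.6e-06, and adjusted p = 0.36 with an estimated correlation), among them Lgals3 at 1.72 ± 0.161 against 42.5 ± 3.14 FPKM and C1qb at 13.4 ± 1.54 against 139 ± 17.7 FPKM. Of 16 collagen and matrix genes 15 fell and none rose (camera adjusted p = 4.0e-06, and adjusted p = 0.38 with an estimated correlation), with the fibronectin gene Fn1 at 5.17 ± 0.739 against 130 ± 20.8 FPKM. All 8 tested mesothelial markers, genes of the lining of body cavities, fell, 2 of them listed at 0 in brown fat (camera adjusted p = 7.6e-05, and adjusted p = 0.36 with an estimated correlation), with Upk3b at 0.0135 ± 0.0234 against 42.4 ± 8.53 FPKM and Msln at 0.00823 ± 0.00799 against 18.7 ± 5.36 FPKM. These 3 counts were the same adjusted over each list alone. Fast twitch muscle genes were higher in brown than in white fat, 11 of 13 over all genes and 12 adjusted over the list alone (camera adjusted p = 0.0061, and adjusted p = 0.60 with an estimated correlation). The genes common to skeletal muscle, with 11 of 23 higher and 1 lower (10 and 0 adjusted over the list alone), did not stand out (camera adjusted p = 0.093). They passed without brown fat replicate 1 (0.013) and with a pseudocount of 0.1 (0.019), over a range of 0.013 to 0.78 in camera tests. The slow twitch genes, with 5 of 12 higher, 1 of them listed at 0 in white fat, and 2 lower, the same adjusted over the list alone, did not stand out either (camera adjusted p = 0.45). Fast twitch genes varied widely between the brown fat libraries, the troponin gene Tnnc2 standing at 7.05, 54.8 and 26.3 FPKM in replicates 1, 2 and 3 and Pvalb at 4.65, 44.0 and 23.3 FPKM.

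The study's title concerns a demethylase of histone H3 lysine 27, the residue that the Polycomb repressive complex 2 methylates. The gene of that demethylase was in the fixed list described next, but its values are not reported here. Of 12 tested genes of the demethylases and of that complex, 6 were higher and 2 lower in brown than in white fat, the same adjusted over the list alone, and the list did not stand out (camera adjusted p = 0.48). Ezh2, a methyltransferase gene, stood at 3.63 ± 0.496 against 2.33 ± 0.502 FPKM (log2 difference 0.48, SE 0.12, limma adjusted p = 0.0032) and Suz12 at 10.01 ± 0.175 against 6.71 ± 0.231 FPKM. The demethylase gene Kdm6a at 3.71 ± 0.168 against 3.01 ± 0.286 FPKM (limma adjusted p = 0.061) and the methyltransferase gene Ezh1 at 10.7 ± 2.13 against 13.3 ± 1.68 FPKM (limma adjusted p = 0.056) did not pass. With TPM rescaling the difference was 0.05 log2 units for Ezh2 (adjusted p = 0.76, range over its alternatives 0.00044 to 0.76, and 0.056 with 6 libraries chosen after the values were seen), -0.01 for Suz12 (adjusted p = 0.90, range 1.1e-05 to 0.90) and -0.26 for Kdm6a. Over the alternatives the adjusted p of Kdm6a ran from 0.0071 to 0.25. It passed with quantile normalization (0.0071), without soleus replicate 3 (0.017), with those 2 tissues alone in the fit (0.025), with array weights (0.040), with the replicate number as a block (0.043) and with a pseudocount of 5 (0.047). That of Ezh1 ran from 0.00017 to 0.22. It passed with TPM rescaling (0.00017), with libraries matched by their residuals as a block (0.014), with upper quartile scaling (0.019), array weights (0.020) or quantile normalization (0.020). It also passed without white fat replicate 2 (0.023) or brown fat replicate 2 (0.024). The list's median was 0.24 log2 units and turned to -0.28 with TPM rescaling. Hox genes of paralog groups 6 to 13, which mark position along the body axis, were lower in brown fat in 6 of 11 tested cases and higher in 1, the same adjusted over the list alone (camera adjusted p = 0.048, and adjusted p = 0.38 with an estimated correlation). This list missed the threshold without brown fat replicate 1 (camera adjusted p = 0.061), brown fat replicate 3 (0.0502) or white fat replicate 3 (0.057), and with a pseudocount of 0.1 (0.0503) or median of ratios scaling (0.059), over a range of 0.0039 to 0.38 in camera tests. With libraries matched by their residuals as a block, a choice made after the residuals were seen, it missed at 0.051. Hoxc8 stood at 1.396 ± 0.0867 FPKM in brown and 41.0 ± 3.13 FPKM in white fat. Of 6 tested genes of groups 1 to 5, 3 were higher and 1 lower, and the list did not stand out (camera adjusted p = 0.72), with a median of 0.21 log2 units where fry pointed down. Hoxa4 stood at 4.52 ± 1.44 against 1.31 ± 0.264 FPKM and Hoxb5 at 0.388 ± 0.0526 against 2.91 ± 0.152 FPKM.

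**Figure D3:**
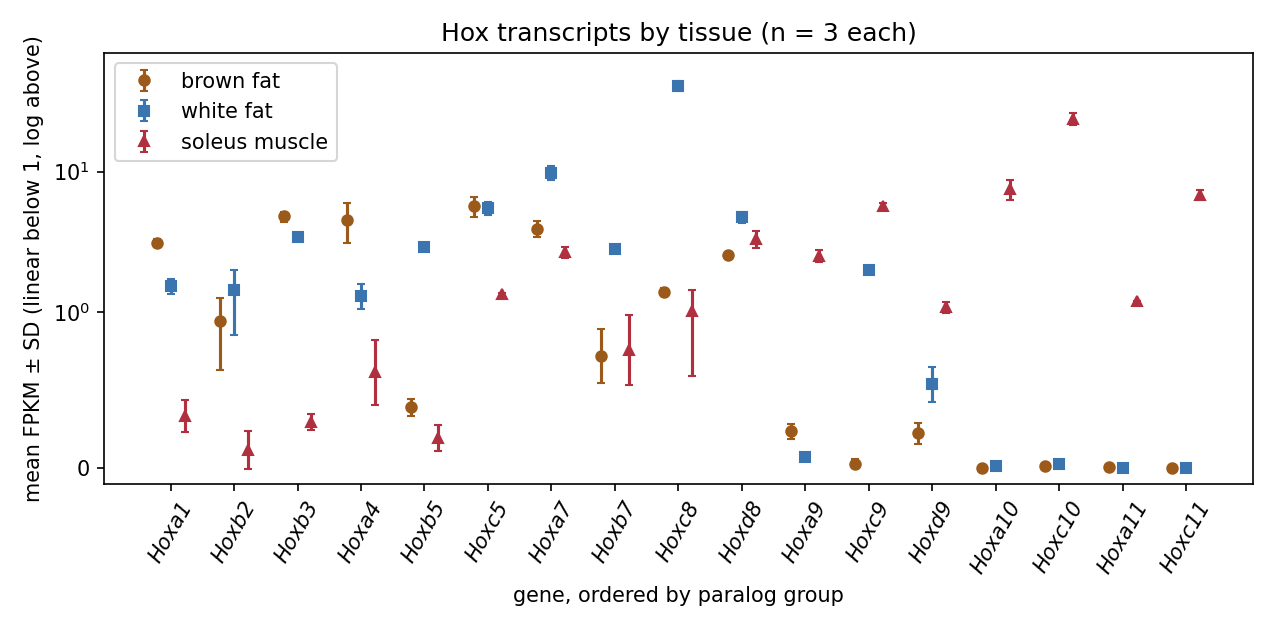
Mean FPKM ± SD over 3 libraries for 17 Hox genes, ordered by paralog group, on an axis that is linear below 1 FPKM and logarithmic above. Hoxc8 is highest in white fat at 41.0 FPKM, and Hoxc10 reaches 23.7 FPKM in soleus against 0.0096 in brown and 0.0256 in white fat.

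Brown fat against soleus muscle set 2 tissues rich in mitochondria side by side. Ucp1 stood at 3685 ± 377 FPKM in brown fat and 2.06 ± 1.85 FPKM in soleus, Cidea at 2193 ± 149 against 7.29 ± 1.33 FPKM, and Pck1, a gene of glycerol synthesis in fat, at 1863 ± 133 against 7.73 ± 6.90 FPKM. Apoc1, an apolipoprotein gene, stood at 1481 ± 142 against 7.94 ± 6.11 FPKM and the transketolase gene Tkt at 1041 ± 53.2 against 5.42 ± 3.19 FPKM. Contractile genes of slow fibres led in the other direction, with Myl2 at 0.955 ± 0.833 FPKM in brown fat and 9797 ± 1132 FPKM in soleus, Myl3 at 1.53 ± 0.138 against 6689 ± 512 FPKM, and Tnnc1 at 0.955 ± 0.352 against 4117 ± 290 FPKM. Over all genes, 5246 were higher and 2535 lower in brown fat at an adjusted p under 0.05 (limma), 2141 and 1121 of them by at least 1 log2 unit, of which 14 and 29 rested on a tissue listed at 0. These 2 numbers were 1192 and 659 with a pseudocount of 5, the higher one was 1425 with median of ratios scaling, and the lower one was 741 without soleus replicate 2. The median log2 fold change of all genes was 0.29, and median of ratios scaling brought it to -0.04. The share of called genes that were higher in brown fat was then 47.5% in place of 67.4%, and the lower genes rose to 4004.

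All 12 tested slow twitch genes fell in brown fat against soleus, with a median of -8.64 log2 units (camera adjusted p = 4.1e-11, and adjusted p = 0.27 with an estimated correlation). Of 13 fast twitch genes 12 fell (camera adjusted p = 3.6e-07, and adjusted p = 0.39 with an estimated correlation), as did 20 of 23 genes common to skeletal muscle (camera adjusted p = 1.6e-11, and adjusted p = 0.36 with an estimated correlation). The higher ones in these lists were those listed at 0 in soleus, Tnnt3 among the fast genes and Acta1, Ckm and Mb among the common ones. Of 13 myogenic regulators 12 fell, 1 of them listed at 0 in brown fat (camera adjusted p = 1.2e-08, and adjusted p = 0.27 with an estimated correlation), with the cofactor gene Vgll2 at 0.0494 ± 0.0318 against 82.8 ± 13 FPKM and the myogenic factor gene Myf6 at 0.105 ± 0.0937 against 58.9 ± 7.47 FPKM. Of 22 genes common to fat 20 rose (camera adjusted p = 0.00062, and adjusted p = 0.42 with an estimated correlation), and the 1 lower gene, Fabp4, was listed at 0 in brown fat. The thermogenic list was higher for 18 of 23 genes and lower for 2 (camera adjusted p = 0.0021, and adjusted p = 0.50 with an estimated correlation). The lower ones were Fabp3, which encodes a fatty acid carrier, at 58.1 ± 18.1 against 290 ± 7.24 FPKM, and the nuclear receptor gene Esrrg at 5.31 ± 0.691 against 14.8 ± 2.87 FPKM. Each of these counts was the same adjusted over the list alone. Fat transcripts varied between the soleus libraries, Adipoq standing at 77.1, 31.8 and 12.4 FPKM in replicates 1, 2 and 3.

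Fatty acid oxidation was higher in brown fat than in soleus for 14 of 15 genes with a median of 2.17 log2 units (camera adjusted p = 0.00028, and adjusted p = 0.36 with an estimated correlation), Acaa2 standing at 1709 ± 68.8 against 283 ± 11.1 FPKM and Acadl at 1615 ± 68.5 against 306 ± 15.2 FPKM. The tricarboxylic acid cycle was higher for 17 of 19 genes (camera adjusted p = 0.0012, and adjusted p = 0.50 with an estimated correlation), with Dlst at 563 ± 14.5 against 121 ± 8.20 FPKM, while Idh2 was lower at 215 ± 30.8 against 664 ± 64.4 FPKM. Complexes II and III had 11 of 14 genes higher and none lower, 6 and 1 with median of ratios scaling, and did not stand out (camera adjusted p = 0.086). Complex I had 14 genes higher, 6 lower and 15 not called, and did not stand out (camera adjusted p = 0.81, in the downward direction). Its median of 0.14 log2 units turned to -0.31 with median of ratios scaling, and also fell under 0 with upper quartile and quantile scaling. Complex IV held subunits that went opposite ways, 7 higher and 2 lower (camera adjusted p = 0.93), and its median of 0.35 log2 units turned to -0.09 with median of ratios scaling. Camera pointed up for this list but down without soleus replicate 1 (median 0.30) or replicate 3 (median 0.31). Cox6a1 stood at 3659 ± 151 FPKM in brown fat and 105 ± 11.6 FPKM in soleus, whereas Cox6a2, the muscle form of the same subunit, stood at 2.91 ± 2.58 against 2954 ± 355 FPKM. Cox8b was high in both, at 6387 ± 305 and 4710 ± 791 FPKM (limma adjusted p = 0.25), and passed when those 2 tissues alone were fitted (adjusted p = 0.012) and with quantile normalization (0.031), over a range of 0.012 to 0.99. Of the ATP synthase genes 4 were higher and 6 lower (camera adjusted p = 0.019, and adjusted p = 0.65 with an estimated correlation), Atp5b at 3788 ± 77.5 against 2007 ± 120 FPKM and Atp5g1 at 1.46 ± 0.176 against 282 ± 41.7 FPKM. Counts for these lists were the same adjusted over the list alone.

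**Figure D4:**
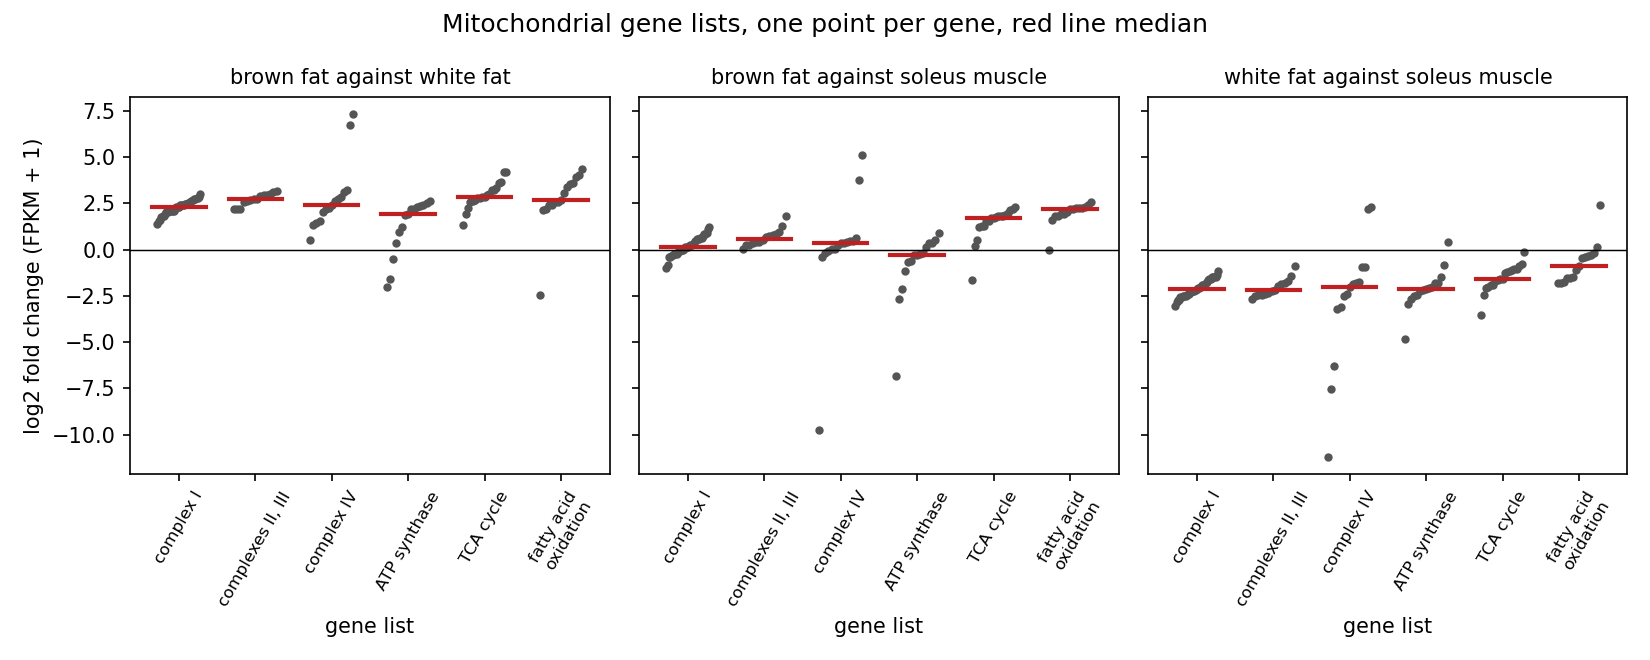
Log2 fold change on FPKM + 1 of each gene of 6 mitochondrial lists in the 3 comparisons, 1 point per gene, with the median of each list as a red line. Complex I has a median of 2.33 in brown against white fat, 0.14 in brown fat against soleus, a value that turns negative with 3 other scalings, and -2.14 in white fat against soleus.

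All 6 tested Hox genes of groups 1 to 5 were higher in brown fat than in soleus, a list that missed the threshold (camera adjusted p = 0.069) but passed without brown fat replicate 2 (0.044) and with median of ratios scaling (0.021), over a range of 0.021 to 0.41 in camera tests. Among them was Hoxb3 at 4.79 ± 0.386 against 0.296 ± 0.0506 FPKM. Of 11 genes of groups 6 to 13, 8 were lower, 2 of them listed at 0 in brown fat, and 1, Hoxa7, was higher (camera adjusted p = 0.00023, and adjusted p = 0.27 with an estimated correlation). Without soleus replicate 1, 2 or 3 this list did not pass (camera adjusted p = 0.33, 0.15 and 0.20, over a range of 0.00019 to 0.33 in camera tests). A filter on 3 libraries can then remove genes found in soleus alone, but the list was not tested with a filter on 2. Hoxa7 did not pass with upper quartile (adjusted p = 0.15), median of ratios (0.47) or quantile scaling (0.22), over a range of 0.0013 to 0.47. Hoxc10 stood at 0.0096 ± 0.0166 FPKM in brown fat and 23.7 ± 2.25 FPKM in soleus. Both counts were the same adjusted over the list alone. Suz12 at 10.01 ± 0.175 against 3.99 ± 0.192 FPKM and Ezh2 at 3.63 ± 0.496 against 1.41 ± 0.157 FPKM were higher in brown fat (limma adjusted p = 2.8e-08 and 2.0e-05). Their list had 8 of 12 genes higher and 1 lower, also adjusted over the list alone, and did not stand out (camera adjusted p = 0.53).

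White fat against soleus muscle set a tissue of storage against one of contraction. Cidec, a lipid droplet gene, stood at 1598 ± 6.00 FPKM in white fat and 21.5 ± 20.9 FPKM in soleus, Adipoq at 2876 ± 266 against 40.4 ± 33.2 FPKM, and the transferrin gene Trf at 1614 ± 222 against 21 ± 16.5 FPKM. In the other direction Myl2 stood at 0.0065 ± 0.0112 FPKM in white fat and 9797 ± 1132 FPKM in soleus, and the fast troponin genes Tnni2 at 0.640 ± 0.255 against 9264 ± 1024 FPKM and Tnnc2 at 0.844 ± 0.387 against 10208 ± 1066 FPKM. Over all genes, 5403 were higher and 2948 lower in white fat at an adjusted p under 0.05 (limma), 2678 and 1406 of them by at least 1 log2 unit, of which 7 and 44 rested on a tissue listed at 0. With a pseudocount of 5 these numbers were 1289 and 930, and with TPM rescaling the higher one was 5298. The median log2 fold change of all genes was 0.35, with 0.01 under median of ratios scaling and 0.93 under TPM rescaling. The share of called genes that were higher in white fat was 64.7%, with 50.1% and 79.6% under those scalings and 52.3% under quantile normalization.

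Most respiratory chain genes were lower in white fat than in soleus. All 35 tested complex I genes fell (median -2.14, camera adjusted p = 4.0e-14), as did all 14 of complexes II and III (median -2.19, camera adjusted p = 1.1e-07), 13 of 15 of complex IV (camera adjusted p = 3.8e-05), 14 of 15 of ATP synthase (camera adjusted p = 1.1e-06) and 18 of 19 of the tricarboxylic acid cycle (camera adjusted p = 2.8e-08). With an estimated correlation these 5 lists had an adjusted p = 0.38, 0.38, 0.39, 0.39 and 0.36. Ndufb5 of complex I stood at 64.5 ± 7.85 against 541 ± 82.9 FPKM, Uqcrq of complex III at 287 ± 47.8 against 1827 ± 224 FPKM, and Idh2 at 56.9 ± 9.47 against 664 ± 64.4 FPKM. The higher complex IV genes were Cox6a1, at 520 ± 63.4 against 105 ± 11.6 FPKM, and Cox8a, at 642 ± 107 against 136 ± 14.1 FPKM, the forms found outside muscle. Fatty acid oxidation was lower for 12 of 15 genes (camera adjusted p = 0.00062, and adjusted p = 0.36 with an estimated correlation), and Cpt1a was higher at 15.4 ± 0.134 against 2.06 ± 0.382 FPKM. Glycolysis was lower for 13 of 18 genes and higher for 5 (camera adjusted p = 0.0027, and adjusted p = 0.36 with an estimated correlation). Pgam2 stood at 0.0502 ± 0.0870 against 1180 ± 68.4 FPKM and Pfkl at 19.3 ± 2.52 against 2.66 ± 0.422 FPKM. Counts for all of these lists were the same adjusted over the list alone.

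White fat was higher for 18 of 23 genes of the white fat list and lower for 3, 1 of them (Cfd) listed at 0 in white fat (camera adjusted p = 0.031, and adjusted p = 0.54 with an estimated correlation). This list missed the threshold without white fat replicate 1 (0.064) or replicate 3 (0.055), over a range of 0.0055 to 0.54 in camera tests. Retn stood at 2526 ± 474 against 41.8 ± 37.4 FPKM, and 1 of the lower genes, Hoxc10, at 0.0256 ± 0.0254 against 23.7 ± 2.25 FPKM. Of the genes common to fat 18 of 22 were higher and 3 lower, and 2 of the lower ones, Fabp4 and Lpl, were listed at 0 in white fat (camera adjusted p = 0.034, and adjusted p = 0.60 with an estimated correlation). All 11 tested macrophage markers (camera adjusted p = 0.00094, and adjusted p = 0.41 with an estimated correlation) and 15 of 16 collagen and matrix genes (camera adjusted p = 0.016, and adjusted p = 0.60 with an estimated correlation) were higher. C1qb stood at 139 ± 17.7 against 10.4 ± 1.74 FPKM and Sparc, a matrix protein gene, at 1346 ± 230 against 225 ± 38.9 FPKM. All 12 slow twitch genes, 12 of 13 fast twitch genes and 20 of 23 common muscle genes were lower (camera adjusted p = 9.4e-10, 2.6e-07 and 4.1e-11), at an adjusted p = 0.27, 0.39 and 0.37 with an estimated correlation. Of the lower genes 1 slow twitch gene (Csrp3) and 1 common gene (Chrna1) were listed at 0 in white fat. The 1 higher common gene, Acta1, was listed at 0 in soleus. Counts were the same adjusted over each list alone. Ezh1 was higher in white fat at 13.3 ± 1.68 against 5.99 ± 0.188 FPKM (log2 difference 1.03, SE 0.13, limma adjusted p = 2.5e-05).

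Genes higher in 1 tissue than in both others by at least 1 log2 unit numbered 636 for brown fat, 1072 for white fat and 859 for soleus. With a pseudocount of 5 these were 393, 505 and 559. The white fat number was 2620 with TPM rescaling and 706 with a filter at 5 FPKM. The soleus number was 537, 502 and 510 without soleus replicate 1, 2 and 3, and 885, 845 and 851 when the filter then asked for 2 libraries in place of 3, a change made after those counts were seen. In the main fit 13, 11 and 53 of them rested on another tissue listed at 0. Ranked by the smaller of the 2 fold changes among genes with at least 10 FPKM, the leading brown fat genes were Ucp1, Cidea, Otop1, Slc27a2, Aspg, S100b, Kng2, Ppp1r3b, Kcnk3 and Elovl3. Slc27a2, a fatty acid transporter gene, stood at 63.9 FPKM in brown fat, 0.570 in white fat and 0.0237 in soleus, and the potassium channel gene Kcnk3 at 95.2, 2.47 and 0.121 FPKM. White fat genes were led by Nnat, Sncg, Slpi, Retnla, Sult1e1, Upk3b, Trf, Agt and Ccdc80, and by Fasn, which was listed at 0 in brown fat. Retnla, a gene of the resistin family, stood at 1600 FPKM in white fat, 32.3 in brown fat and 37.0 in soleus. Soleus genes were led by Myl2, Myl3, Tnnc1, Tnnt1, Myoz2, Cox6a2 and Actn2, by Ckmt2 and Csrp3, which were listed at 0 in white fat, and by Fabp4. Fabp4, a gene of the list common to fat, was listed at 0 in both brown and white fat. Its place here rests on those zeros. Genes lower than in both others numbered 206 for brown fat, 443 for white fat and 1304 for soleus.

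The overlaps of the 3 comparisons, which share libraries, were set against independent lists. These overlaps are the same genes as those counted above as higher or lower than in both others. A gene changed in the common tissue alone enters both lists, so independence is not the level of chance. Brown fat and soleus were both higher than white fat for 443 genes, where 175 would be shared by independent lists of that size. They were both lower for 1072 (375 if independent). Across genes, which are not independent replicates, the 2 sets of fold changes correlated at 0.457 with a covariance of 0.871, where shared libraries alone gave 0.50 and 0.0071 in simulated unchanged tissues. Changes confined to the common tissue also raise this covariance, so its excess does not show a change that the 2 others share. Brown and white fat were both lower than soleus for 859 genes (159 if independent) and both higher for 1304 (578 if independent), with a correlation of 0.751 and a covariance of 1.93. White fat and soleus were both higher than brown fat for 206 genes (157 if independent) and both lower for 636 (266 if independent), with a correlation of 0.245 and a covariance of 0.429. Part of each excess may come from the shared libraries, which were too few to split. In simulated unchanged tissues the mean number of selective genes was 0 for brown fat and soleus and 0.02 for white fat over 50 simulations. These simulations had independent noise and no offset in scaling or failed estimate. A number near 0 was thus set by their design and lends no weight to the counts of selective genes.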

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

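Chosen after the data were seen were the tests without genes listed at 0, with 6 libraries (without brown fat replicate 2, white fat replicate 3 and soleus replicate 1, the highest of their tissue in muscle transcripts, Ucp1 and fat transcripts), with a filter on 2 libraries when 1 soleus library was left out, and with libraries matched by their residuals, and all alternatives for counts of genes changed by at least 1 log2 unit. All 147 gene differences named here and in the comparisons kept their direction and their side of the threshold under the alternatives that gave a value, except Kdm6a, Ezh1, Ezh2 and Suz12 between brown and white fat and Hoxa7 and Cox8b between brown fat and soleus. With TPM rescaling Suz12 turned to -0.013 and Kdm6a to -0.26 log2 units, genes called between brown and white fat went from 3769 higher and 3446 lower to 1898 and 6993, and white fat had 2620 selective genes in place of 1072. Genes changed by at least 1 log2 unit went from 1232 higher and 1387 lower in brown than in white fat to 813 and 3352, and from 2678 to 5298 higher in white fat than in soleus. That scaling moved the median of all genes between brown and white fat from 0.03 to -0.52, and 477 genes were called in the other direction. Median of ratios scaling gave 4004 genes lower in brown fat than in soleus in place of 2535, where it moved the median of all genes from 0.29 to -0.04, and 1425 genes higher by at least 1 log2 unit in place of 2141. A filter at 5 FPKM left 6743 genes to test, and gave 2062 lower in brown than in white fat, 891 of them by at least 1 log2 unit, 3511 higher in white fat than in soleus in place of 5403, and 706 selective for white fat. A pseudocount of 5, which shrinks fold changes, gave 393, 505 and 559 genes selective for brown fat, white fat and soleus in place of 636, 1072 and 859, and of genes changed by at least 1 log2 unit 773 higher and 631 lower in brown than in white fat, 1192 and 659 in brown fat than in soleus, and 1289 and 930 in white fat than in soleus. Leaving out 1 library at a time gave 502 to 865 genes selective for soleus, the low values without soleus replicate 1 (537), 2 (502) or 3 (510), because fewer libraries could pass a filter on 3. With the filter on 2 libraries they were 885, 845 and 851. Genes lower by at least 1 log2 unit in brown fat than in soleus ranged from 741 (without soleus replicate 2) to 1124. Apart from the values given above, the counts of genes called, changed by at least 1 log2 unit or selective for a tissue stayed within 1.5 times under each alternative run. Without genes listed at 0 the called genes were 3762 higher and 3437 lower in brown than in white fat, and with the 6 libraries 3158 and 3099, where Ezh2 missed the threshold (log2 difference 0.33, adjusted p = 0.056, over a range of 0.00044 to 0.76). Of 108 gene list tests camera called 61, camera with an estimated correlation 0 (14 at an unadjusted p under 0.05) and fry 97, and the cause was not tested. Of 60 list tests described, median of ratios scaling left 54 unchanged in direction and call, and a pseudocount of 0.1 left 57. Those of fatty acid synthesis and peroxisomal genes between white fat and soleus were not among them. The complex IV list between brown fat and soleus, which was not called, turned with median of ratios scaling (median -0.093), with the 6 libraries (median 0.30, the test pointing down) and without soleus replicate 1 or 3 (over all libraries left out the median was 0.30 to 0.41). So did the developmental transcription factors between brown and white fat, with a pseudocount of 0.1 (median 0.31), the 6 libraries (0.14) and without white fat replicate 1, 2 or 3 (over all libraries left out the median was -0.017 to 0.26). Fry pointed the other way from camera for Hox groups 1 to 5 between brown and white fat (median 0.21) and complex I between brown fat and soleus (median 0.14), and the cause of these turns was not tested. With the replicate number as a term (replicate block) 3643 genes were higher and 3374 lower in brown than in white fat, and all 60 list tests kept their direction and call. Of 9 same-number pairs of libraries from 2 tissues 0 had residuals correlated above 0.1, but 6 of 18 pairs with different numbers did, the highest being white fat replicate 1 with soleus replicate 2 (0.361), so shared mice under other numbers stay open. Libraries were then matched by these correlations, though not every matched pair was correlated, brown fat replicate 2 with soleus replicate 1 standing at -0.073. The match came from the residuals of these same libraries, so it cannot test whether they share mice. With this match as a term, 3779 genes were higher and 3467 lower in brown than in white fat, and 5429 and 2971 in white fat than in soleus. The Hox groups 6 to 13 between brown and white fat missed the threshold (adjusted p = 0.051, over a range of 0.0039 to 0.38 in camera tests). Depth limits genes of low value, but with read totals not given no bound on an undetected transcript could be computed.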

Other observations

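Chosen only after the result was seen were the tests on the order of muscle genes in brown fat, on fibre types, on genes listed at 0 and on Ucp1 in white fat. Gene groups of lipid and sugar handling also differed between brown fat and other tissues by camera with a preset correlation. Between white fat and soleus the lists of fatty acid synthesis and of peroxisomal genes did not stand out (camera adjusted p = 0.093 and 0.14). Genes that make fatty acids were higher in brown than in white fat for 9 of 15 tested and lower for 1, Fasn, listed at 0 in brown fat (camera adjusted p = 0.014, and adjusted p = 0.54 with an estimated correlation). Acly, which makes acetyl-CoA in the cytosol, stood at 727 ± 137 FPKM in brown fat, 83.3 ± 20.5 in white fat and 5.41 ± 1.59 in soleus, and the fatty acid elongase gene Elovl6 at 130 ± 12.2, 6.02 ± 1.5 and 0.318 ± 0.138 FPKM (SD, n = 3 libraries each). Peroxisomal genes were higher in brown than in white fat for 12 of 14 and lower for 1, the fatty acid transporter gene Abcd2 at 20.5 ± 6.08 against 118 ± 9.46 FPKM (camera adjusted p = 0.0049, and adjusted p = 0.42 with an estimated correlation), and higher than in soleus for 13 and lower for 1 (camera adjusted p = 0.0021, and adjusted p = 0.39 with an estimated correlation). Counts for these lists were the same adjusted over the list alone. Glycogen genes were higher in brown than in white fat for 12 of 15 and lower for 2, 13 and 2 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.36 with an estimated correlation). Against soleus 4 were higher and 10 lower, the same adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.36 with an estimated correlation), a call lost with median of ratios scaling (adjusted p = 0.074, over a range of 0.0091 to 0.36 in camera tests). The liver form of glycogen phosphorylase, Pygl, stood at 359 ± 7.73 FPKM in brown fat, 67.9 ± 6.17 in white fat and 1.41 ± 0.940 in soleus, and the muscle form Pygm at 4.72 ± 3.19, 1.09 ± 0.265 and 669 ± 44.8 FPKM.

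Of 16 developmental transcription factors other than Hox 8 were lower in brown fat than in soleus, 1 of them listed at 0 in brown fat, and 4 higher, and 10 were lower in white fat than in soleus and 4 higher, the same adjusted over the list alone (camera adjusted p = 0.0092 and 0.015, and adjusted p = 0.27 and 0.32 with an estimated correlation). In white fat 7 were higher and 7 lower with TPM rescaling, and both calls were lost with median of ratios scaling (adjusted p = 0.067 and 0.097) and without soleus replicate 1 (0.33 and 0.37), 2 (0.24 and 0.32) or 3 (0.26 and 0.32), over ranges of 0.0024 to 0.33 and 0.00066 to 0.37 in camera tests. Without a soleus library the filter on 3 libraries can remove genes found in soleus alone here too, which was not tested for this list. Between brown and white fat 6 were higher and 5 lower, 1 of them listed at 0 in brown fat, the same adjusted over the list alone (camera adjusted p = 0.92), with a median of 0.13 log2 units where camera and fry pointed down, and camera turned up without white fat replicate 1, 2 or 3 (adjusted p = 0.58, 0.47 and 0.44, over a range of 0.44 to 0.96 in camera tests). Tbx15 stood at 27.1 ± 4.45 FPKM in soleus, 0.890 ± 0.185 in brown fat and 0.0305 ± 0.0151 in white fat, and Gata6 at 6.08 ± 0.228 in white fat, 0.307 ± 0.0327 in brown fat and 0.116 ± 0.0958 in soleus. Endothelial markers were higher in brown than in white fat for 7 of 10 and lower for 1, the same adjusted over the list alone, but 3 each way with TPM rescaling, and the list did not stand out (camera adjusted p = 0.10). The receptor gene Kdr stood at 19.4 ± 1.16 FPKM in brown fat, 6.17 ± 1.43 in white fat and 5.56 ± 0.704 in soleus. Of 17 ribosomal protein genes 14 were lower in brown fat than in soleus and none higher, the same adjusted over the list alone (camera adjusted p = 0.00084, and adjusted p = 0.60 with an estimated correlation). Reads of these genes may fit several places, so their values are uncertain. Of 9 interferon response genes 8 were higher in white fat than in soleus and none lower, the same adjusted over the list alone (camera adjusted p = 0.037, and adjusted p = 0.41 with an estimated correlation), a call lost without white fat replicate 1 (0.052) or 3 (0.053) and without soleus replicate 2 (0.055) or 3 (0.066), over a range of 0.018 to 0.41 in camera tests. Of 13 stress and immediate early genes 9 were lower in white fat than in soleus and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.0084, and adjusted p = 0.45 with an estimated correlation), and Nr4a1 stood at 2.35 ± 0.785 FPKM in white fat, 53.9 ± 10.3 in soleus and 121 ± 65.9 in brown fat.

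Genes named for seminal vesicle secretions, chosen after their values were seen, stood in white fat replicate 1. Svs2 was at 77.3, 3.87 and 0.0546 FPKM in white fat replicates 1, 2 and 3, Sva at 18.3, 0.303 and 0 FPKM, and Pate4 at 16.1, 1.05 and 0.0308 FPKM. In soleus replicates 1, 2 and 3 Svs2 was at 0.0553, 0.962 and 0.135 FPKM and Pate4 at 0.0234, 0.963 and 0 FPKM.

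Muscle transcripts in the brown fat libraries may come from skeletal muscle carried into the samples. The order replicate 2 over 3 over 1 was read from Ckm in these same libraries. Of 43 other muscle list genes 35 (81.4%) followed it. A share of 16.7% by chance would hold only for an order set beforehand and for independent genes, and neither was the case. Muscle genes expressed by brown fat itself could also share an order, so this count does not separate the 2 sources. Muscle with the fibre makeup of the soleus samples was also examined. A first test over 12 fast and 12 slow genes missed the threshold (two-sided exact rank p = 0.089) and was then limited to abundant genes. Among genes with at least 1000 FPKM in soleus, 7 of the fast twitch list stood at a median of 0.365% of the soleus level and 6 of the slow twitch list at 0.0230%, a difference of 3.98 log2 units that was 3.29, 4.42 and 4.15 in brown fat replicates 1, 2 and 3. Of the 6 slow genes 5 lay under all 7 fast genes, Myl2 at 0.00974% against Tnnc2 at 0.288%, and the exception was Fhl1 at 2.45% (two-sided exact rank p = 0.051). A muscle of other fibre makeup near the fat stays open, and so does expression by cells of brown fat itself, which was not tested.

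Abundant genes listed at 0 may reflect estimates that failed, and that fat in general does not transcribe them was argued against for Cfd and Scd1. In soleus, fat genes were higher in replicate 1 than in 3, and Cfd and Scd1 followed them with log2 ratios of 2.06 and 2.63, inside the range of 0.26 to 3.40 of 11 fat genes. Among 8522 genes at 1 FPKM or more in soleus, 32 others had a ratio at least that high, and 29 of these were at least 10 times higher in white fat than in soleus. Since the fat in soleus need not be the white fat sampled, absence from that tissue stays open, as do a failed estimate, reads shared with copies of the gene and a filter of the authors, none of which was tested. Genes listed at 0 in a tissue but at 10 FPKM or more in another numbered 10 for brown fat, 27 for white fat and 8 for soleus. Those at 10 FPKM or more in both other tissues numbered 1, 4 and 2. The larger counts include muscle genes listed at 0 in white fat, such as Myod1 and Myf6, so they do not measure failed estimates.

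Ucp1 in white fat replicate 3 may come from brown fat carried into that sample. Other genes were taken at 50 FPKM or more in brown fat and at least 50 times lower in 1 white fat replicate, and replicate 3 was compared with the replicate not used for the choice. The 16 genes chosen on replicate 1 exceeded replicate 2 by a median of 1.09% of the brown fat level, with Ucp1 at 0.929%, and 16 of them were higher in replicate 3, against 52.1% of all tested genes. The 15 chosen on replicate 2 exceeded replicate 1 by a median of 0.912%, with Ucp1 at 0.756%, and 14 of them were higher, against 44.2% of all. Most genes were in both sets and both used the same replicate 3, so the 2 results are not independent. Heat-producing cells within white fat would raise the same genes and stay open, as no value here separates them.

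The counts of called genes were set against other splits of the libraries. For each pair of tissues 1 of the 10 splits of its 6 libraries, the real one, gave as many genes, with 7215, 7781 and 8351 called and 0 in the highest other split, but 10 splits are too few for a share under 0.05. For selective genes 100 splits of the 9 libraries were drawn, and the share that gave as many was under 0.05 for each tissue. Brown fat had 636 genes, reached by 4 splits with the real one (highest other 1129), white fat 1072, reached by 2 (highest other 1147), and soleus 859, reached by 3 (highest other 1129). Each other split that reached these counts had a whole tissue as its group, and groups mixed from several tissues reached at most 0. The share thus followed how often a draw kept a whole tissue as the group. It restates that the tissues differ and does not decide whether such counts arise by chance.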
